A study of Homo sapiens with 8 samples.

How the data were processed

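The values were read from the submitters' table of 54675 probe sets on 8 HG-U133 Plus 2.0 arrays, which the submitters describe as normalised by RMA (robust multi-array average) and which held log2 signals between 3.68 and 15.6. The RMA version is not given in the sources used here, and the raw array images were not used here. No further normalisation was applied before the tests. The 62 control probe sets were set aside, 41091 probe sets carried 1 gene symbol, 1801 carried several and 11721 carried none. Each of 19775 genes was read by the probe set with the highest mean over all 8 arrays among those with 1 symbol; 10523 genes had more than 1 such probe set, and 5716 genes were read by a probe set of the _x_at or _s_at kind, which can match more than 1 transcript. Of the gene symbols, 40 were not in the reference annotation and 0 were updated. No dim genes were removed in the tests reported, so the precision of low signals is limited by background, and the number of arrays limits the precision of all values.

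A linear model with 4 group means (vehicle and DHT for 4, 16 and 48 h, n = 2 each) was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, so that the groups shared a spread (4 residual and 7.21 prior degrees of freedom). The 3 DHT groups were compared with vehicle, and with each other, which tests whether the DHT groups differed between times. Benjamini-Hochberg adjustment ran over all genes in each comparison, and a gene was called at adjusted p below 0.05. A moderated F test over the 3 comparisons with vehicle asked whether a gene changed at any time. Tests were two-sided. For 2 arrays against 2, an exact permutation test cannot go below 0.333, so no single-gene permutation test was run. Errors of a log2 change are standard errors from limma. The replicate numbers were not used in the model, since nothing in the labels says that they mark a common day.

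The design, the 26 gene lists, the rule for naming genes and the alternative settings were chosen before the data were examined, unless the text says otherwise. The rule took the 8 highest and 8 lowest called log2 changes of each comparison with vehicle. It also took the 4 highest and 4 lowest of each comparison between times, and up to 4 called members with the largest change of each list. FKBP5, KLK3, WNT7B, ERBB2, ERBB3, MYC and PIP were always taken. Of all genes the rule took, 100 are named in the text. Counts of named genes and of their calls rest on these. The lists covered classical androgen response, glucocorticoid-shared steroid response, apocrine differentiation, luminal identity, ERBB receptors with ligands and adaptors, ERK pathway output, WNT ligands and receptors, WNT/beta-catenin targets, G1/S replication genes, G2/M mitotic genes, ribosome biogenesis and MYC targets, cholesterol synthesis and uptake, fatty acid synthesis and storage, endoplasmic reticulum folding and the unfolded protein response, ATF4 and amino acid supply, steroid hormone metabolism, interferon-stimulated genes, NF-kB and inflammatory genes, p53 targets, hypoxia and glycolysis, immediate early genes, and markers of basal, mesenchymal, immune and endothelial, and prostate epithelial cells, with a housekeeping list. They held 540 distinct genes, of which 489 were measured and 19 stood in more than 1 list; some listed genes are not analysed here. After the values had been seen, 6 more lists were added: serum response factor targets, YAP and TAZ targets, further hypoxia-inducible genes, the aryl hydrocarbon receptor battery, estrogen-induced genes, and antigen presentation with guanylate-binding proteins.

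Each fixed list was tested against the other genes at each time with camera (limma), with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 78 tests. Camera with a correlation estimated from these arrays, and fry, were run beside it. The preset test called 26 of the 78 results, and with an estimated correlation 0 of the 78 were called, the smallest adjusted p being 0.218; fry called 28 for a shift in 1 direction and 61 for a change in either direction. The fry test for a shift in 1 direction kept 22 of the 26 preset calls and turned 0. Its adjusted p at 48 h was 0.0136 for G2/M genes, 0.0022 for hypoxia and glycolysis and 0.110 for ribosome biogenesis. Fry asks whether list members changed, not whether they changed more than other genes. Because camera with an estimated correlation lost all preset calls, each list below is described by the number of its members called, with the estimated value beside it. A higher correlation is not the reason for every loss. For apocrine differentiation at 48 h the estimate was -0.0095, below the preset, yet the unadjusted camera p rose from 0.00015 to 0.0144. With an estimated correlation camera takes its p from the 4 residual degrees of freedom, a limit that the preset form does not have. Small p values are then hard to reach, so the 0 calls do not show that the lists were unchanged. The lists added after the values had been seen were adjusted among themselves only. Their adjusted p values are therefore not comparable with those of the fixed lists.

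The pipeline was tried on 8 simulated arrays, in which 200 of 19775 genes were changed per DHT group. They were drawn from the vehicle means and the spread of each gene after limma had moved it towards the prior. It recovered all genes changed by 1 or 2 log2 units. Of those changed by 0.5 it recovered 71.6%, 70.1% and 82.1% at 4, 16 and 48 h. False calls were 15 of 196, 17 of 197 and 17 of 205. Genes were simulated as independent and with the same spread in each group. In the real arrays the SD across genes of the replicate difference was 0.147 at 4 h and 0.207 at 16 h.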

Results

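MDA-MB-453, a human breast cancer cell line that lacks estrogen receptor and expresses the androgen receptor, was kept for 3 days in phenol red-free medium with 5% charcoal-stripped serum, which is low in steroids. The cells then received vehicle or 10 nM 5α-dihydrotestosterone (DHT, the potent natural androgen) for 4, 16 or 48 h, and total RNA was hybridised to expression arrays. There were 8 arrays in 4 groups, each with n = 2 biological replicates. The labels give no time for the vehicle arrays, which served as the control at each time, so an effect of DHT is not separated from one of time in culture. The median log2 signal per array ranged from 7.59 to 7.63. Replicates correlated across genes at r = 0.996 for vehicle, r = 0.997 at 4 h, r = 0.995 at 16 h and r = 0.997 at 48 h. Genes are not independent replicates. The first principal component held 51.4% of the variance and ordered the groups by time, with values from -23.1 and -17.8 for vehicle to 22.3 and 17.7 at 48 h. DHT 16 h replicate 2 stood apart on the second component (16.1% of the variance), at -23.1 against -0.51 to 10.8 for the other 7 arrays. It also stood apart in the difference between its 3′ and 5′ control probe sets for ACTB, 1.52 log2 units against 0.203 to 0.945. For GAPDH the difference was 0.817 against 0.185 to 0.349.

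**Figure D1:**
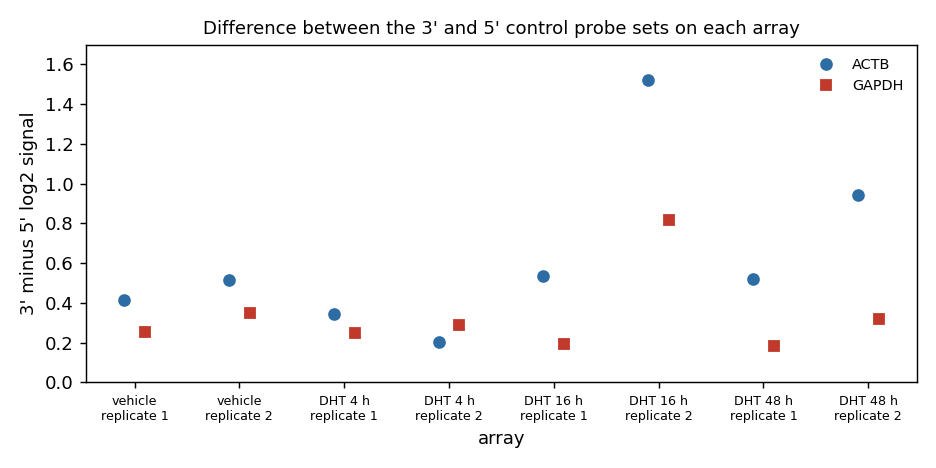
Difference in log2 signal between the 3′ and 5′ control probe sets (vertical axis) of ACTB (circles) and GAPDH (squares) on each of the 8 arrays (horizontal axis). DHT 16 h replicate 2 had the highest value for both, 1.52 and 0.817.

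**Figure D2:**
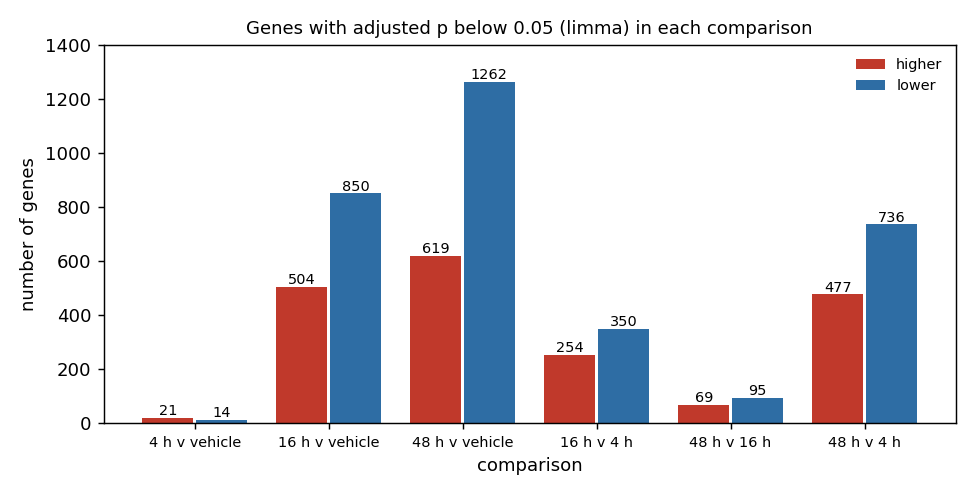
Number of genes (vertical axis) with an adjusted p below 0.05 in each of the 6 comparisons (horizontal axis), with red bars for higher and blue bars for lower. The counts against vehicle went from 21 higher and 14 lower at 4 h to 619 higher and 1262 lower at 48 h.

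The comparison at 4 h asked which genes DHT changed early. AQP3, a water and glycerol channel, rose 4.25-fold, a log2 change of 2.09 ± 0.10 (SE, n = 2, adjusted p = 8.2e-06), while its 2 other probe sets, also bright, gave 0.50 and 0.40 with no call. CLDN8, a tight junction protein, rose by 1.79 ± 0.13, MYC, a transcription factor that drives growth, by 1.67 ± 0.13, and NFKBIA, an inhibitor of NF-kB, by 1.11 ± 0.10. FKBP5, a co-chaperone of steroid receptors and a classical androgen target, rose by 0.98. UGT2B28, which conjugates androgens for excretion, rose by 0.90, EAF2, an elongation factor partner, by 0.87, and CCDC86 by 0.86. The largest fall was in PDE4B, a cyclic AMP phosphodiesterase (log2 change -1.24 ± 0.10, adjusted p = 0.00053), followed by the adhesion protein AMIGO2 (-0.98), FAM43A (-0.97), SHISA2 (-0.91), PHLDB2 (-0.79), SIPA1L2 (-0.74), the ephrin receptor EPHA4 (-0.66) and PPFIBP2 (-0.65).

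The lists fixed in advance held few calls at 4 h. Among ribosome biogenesis and MYC target genes, 1 of 25 rose over all genes and 12 rose adjusted over the list alone, with 22 of 25 log2 changes above 0 (adjusted p = 0.218 with an estimated correlation). Its called member was NOP16, a nucleolar protein (0.67), and WDR43 had 0.76 with no call. In the glucocorticoid-shared steroid response list 2 of 17 rose, FKBP5 and NFKBIA, and 3 rose adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). In the classical androgen response list 2 of 33 rose, FKBP5 and the protease ADAMTS1 (0.82), and 31 were not called. Adjusted over the list alone the counts were 2 higher and 1 lower, and its median and mean log2 change differed in sign (-0.01 and 0.03). Steroid hormone metabolism had 2 of 21 higher, UGT2B28 and HSD11B2, which inactivates cortisol (0.75), with 2 higher and 1 lower adjusted over the list alone and a median of -0.03 against a mean of 0.04. Apocrine differentiation had 1 of 20 higher, UGT2B28, and 1 lower, KMO, an enzyme of tryptophan breakdown (-0.61), with the same counts adjusted over the list alone. MYC was the 1 called member of the WNT/beta-catenin targets (20 measured) and of the immediate early genes (20 measured), where 2 and 3 rose adjusted over each list alone. NFKBIA was the 1 called NF-kB gene of 18, also adjusted over the list alone. For these lists the values with an estimated correlation were adjusted p = 0.910 for classical androgen response and steroid metabolism, 0.959 for apocrine differentiation, 0.480 for WNT targets, 0.218 for immediate early genes and 0.686 for NF-kB. The luminal identity list had 0 of 21 called and 4 lower adjusted over the list alone (adjusted p = 0.252 with an estimated correlation). The ERK pathway output had 0 of 16 called and 2 lower adjusted over the list alone (adjusted p = 0.669 with an estimated correlation). The other 16 lists, among them G1/S and G2/M genes, hypoxia and glycolysis, and all 4 marker lists, had 0 of 294 members called by limma at 4 h, over all genes or adjusted over the list alone, and 27 at an unadjusted p below 0.05. Of these, G2/M genes and endoplasmic reticulum folding genes had been called lower with the preset correlation (adjusted p = 0.741 and 0.557 with an estimated correlation). Medians and means differed in sign, both within 0.02 of 0, for the cholesterol, fatty acid, hypoxia and basal lists. For the immune and endothelial list the test pointed down while median and mean lay above 0, at 4 h and at 16 h.

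In all, 21 genes rose and 14 fell at 4 h among 19775, against 1550 at an unadjusted p below 0.05. With values shifted to equal housekeeping signal the counts were 32 and 13. Other probe sets of the named genes were called in 0 of 26 cases, in a fit adjusted over all probe sets instead of 1 per gene. That fit called 8 higher and 2 lower at 4 h and kept 8 of the main calls. Part of the 0 may therefore come from the adjustment. AQP3, CLDN8, MYC, NFKBIA and PDE4B kept their calls without each of the 8 arrays in turn, and the other 15 named calls at 4 h were lost without at least 1. The count was 7 without vehicle replicate 1, 14 without vehicle replicate 2, 8 and 5 without DHT 4 h replicate 1 and 2, 19 without either 48 h array and 60 without either 16 h array. Without DHT 4 h replicate 2, the array whose removal ended all 15, the calls of FKBP5, FAM43A, AMIGO2, CCDC86, UGT2B28, EAF2, ADAMTS1, SIPA1L2, HSD11B2, PPFIBP2, SHISA2, NOP16, KMO, PHLDB2 and EPHA4 were lost. The highest adjusted p over the 8 fits was 0.0807 for FKBP5 and FAM43A, 0.0914 for CCDC86, 0.113 for AMIGO2, 0.188 for ADAMTS1, 0.199 for SIPA1L2, 0.235 for EAF2, 0.278 for UGT2B28, 0.324 for HSD11B2 and PPFIBP2, 0.349 for SHISA2, 0.396 for NOP16, 0.407 for KMO and PHLDB2, and 0.571 for EPHA4. DHT 4 h replicate 1 and vehicle replicate 1 each ended 13 of them, vehicle replicate 2 ended 10 and each 48 h array ended 6.

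The comparison at 16 h asked what DHT had changed by then. AQP3 rose 51.6-fold (log2 change 5.69 ± 0.10, SE, n = 2, adjusted p = 1.2e-10), and its other probe sets gave 2.69 and 2.99. CYP4F8, a fatty acid hydroxylase, rose 13.4-fold, UGT2B28 12.1-fold, CLDN8 9.58-fold, the stress-responsive NDRG1 6.88-fold, the muscle-type protein MYBPC1 5.69-fold and FKBP5 5.48-fold. The amine-forming decarboxylase DDC rose as well, and its other probe set had a log2 change of 1.17. PALLD, an actin-bundling scaffold, fell by 3.75 log2 units (SE 0.13, adjusted p = 3.1e-08), and 2 other probe sets fell by 3.70 and 3.10, while a dim one read 0.01. Falls followed in the calcium-binding annexin ANXA3 (-2.80), CYP1A1, which oxidises aromatic hydrocarbons (-2.59), SHISA2 (-2.52) and MACC1 (-2.23). The cytoskeletal linker EPPK1 (-2.14), the matrix glycoprotein TNC (-2.08) and the secreted guidance cue SEMA3C (-2.06) came next. Other probe sets of EPPK1 read -1.47 and -2.29, and further ones -0.17 and 0.09 with no call.

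Of 30 G2/M mitotic genes, 23 fell at 16 h, 0 rose and 7 were not called, with 26 lower adjusted over the list alone. CCNA2 (-0.99), the mitotic kinesins KIF23 (-0.96) and KIF20A (-0.89), DLGAP5 (-0.93) and the kinase AURKA (-0.81) were among them. Of 29 G1/S replication genes, 12 fell and 17 were not called, with 1 higher and 18 lower adjusted over the list alone, among them the ribonucleotide reductase subunit RRM2 (-0.96), CCNE2 (-0.84), TYMS (-0.76) and TK1 (-0.72). Both lists had adjusted p = 0.218 with an estimated correlation. The p53 targets had 5 of 17 lower, led by the secreted factor GDF15 (-1.87), with CDKN1A, a brake on the cell cycle, at -0.64 and TP53INP1 at -0.50. 2 were higher and 8 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Another probe set of GDF15, a dim one, read 0.12. Without vehicle replicate 1, CCNE2, DLGAP5, AURKA and TP53INP1 lost their calls, and the highest adjusted p over the 8 fits without 1 array was 0.101, 0.0540, 0.120 and 0.158. Vehicle replicate 2 also ended the calls of AURKA, TP53INP1 and CDKN1A (0.0581), DHT 16 h replicate 1 those of AURKA and TP53INP1, DHT 16 h replicate 2 that of CCNE2, and each 4 h and 48 h array that of TP53INP1. KIF23 and AURKA had no call in a probe set outside the _s_at kind (adjusted p up to 0.967 and 0.573 over all settings).

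At 16 h, of 25 ribosome biogenesis and MYC target genes, 14 rose, 0 fell and 11 were not called, with 19 higher adjusted over the list alone (adjusted p = 0.231 with an estimated correlation). WDR43 rose by 0.82, NOP16 by 0.69, the polyamine enzyme ODC1 by 0.65 and WDR12 by 0.47, and MYC itself by 1.31. Hypoxia and glycolysis genes had 8 of 18 higher, NDRG1 (2.78), BNIP3 (1.42), P4HA1 (1.25), PFKFB4 (1.12) and PDK1 (1.11) among them, and 1 lower, ANKRD37 (-0.60), with 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Fatty acid synthesis and storage had 5 of 18 higher, among them the synthase FASN (0.92), the rate-limiting carboxylase ACACA (0.72) and ACSL1 (0.60), with 6 higher adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Cholesterol synthesis and uptake had 3 of 19 lower, ACAT2 (-0.48) and SC5D (-0.43) among them, and 4 adjusted over the list alone (adjusted p = 0.797 with an estimated correlation). The ATF4 and amino acid list had 3 of 24 higher, with the lipoprotein receptor VLDLR at 1.18 and the asparagine synthetase ASNS at 0.77, and 1 lower, and 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.959 with an estimated correlation; median -0.01, mean 0.06). Endoplasmic reticulum folding had 1 of 21 higher, DNAJB9 (0.43), and 0 adjusted over the list alone (adjusted p = 0.979 with an estimated correlation; median -0.01, mean 0.00). Without vehicle replicate 1 the calls of WDR43, WDR12, ANKRD37, ACSL1, ACAT2, SC5D and DNAJB9 were lost, and the highest adjusted p over the fits without 1 array was 0.0877, 0.0641, 0.105, 0.111, 0.122, 0.129 and 0.205. Vehicle replicate 2 also ended the calls of WDR12, ACSL1 and SC5D, DHT 16 h replicate 1 those of ACSL1 and ACAT2, DHT 16 h replicate 2 those of WDR43 and SC5D, and each of the 8 arrays that of DNAJB9.

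Steroid-response and identity genes were mixed at 16 h. In the classical androgen response list 7 of 33 rose and 4 fell, with 8 higher and 5 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). IQGAP2, a scaffold protein, rose by 2.15, the secreted AZGP1 by 1.18 and ADAMTS1 by 1.29, while KLK3, the prostate-specific antigen gene, had 0.01. The glucocorticoid-shared list had 3 of 17 higher, with TSC22D3 at 0.58, and 1 lower, the EGFR inhibitor ERRFI1 (-0.85), and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Apocrine differentiation had 8 of 20 higher, CYP4F8, UGT2B28 and AZGP1 among them, and 2 lower, with KMO at -1.19, and 9 higher and 4 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). The apocrine secretory protein PIP rose by 0.36. Steroid hormone metabolism had 3 of 21 higher, with HSD11B2 at 2.17 and SRD5A1, which makes DHT, at 0.70, and 1 lower, the sulfatase STS (-0.87), and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Luminal identity had 2 of 21 higher, with KRT19 at 0.58, and 4 lower, with AGR2 at -1.37, TFF1 at -0.72 and CLDN4 at -0.40, and 2 higher and 5 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Without vehicle replicate 1 the calls of PIP, TSC22D3 and CLDN4 were lost, at adjusted p up to 0.238, 0.0544 and 0.173 over the fits without 1 array. Every other array also ended that of PIP, and all but DHT 16 h replicate 2 that of CLDN4. TSC22D3 had no call in a probe set outside the _s_at kind (adjusted p up to 0.631).

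Among ERBB receptors, ligands and adaptors 2 of 18 fell at 16 h, ERBB2 (-0.47) and ERRFI1, also adjusted over the list alone, and ERBB3 had -0.02 (adjusted p = 0.862 with an estimated correlation). ERK pathway output had 3 of 16 lower, the feedback inhibitors SPRY1 (-1.14) and DUSP6 (-0.50) and IER3 (-0.68), and 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.643 with an estimated correlation). WNT ligands and receptors had 2 of 26 higher, WNT7B (0.47) and FZD4 (0.54), and 1 lower, the WNT secretion factor WLS (-0.41), also adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). The WNT/beta-catenin targets had MYC higher and 2 of 20 lower, with JAG1 at -1.13, and 3 higher and 3 lower adjusted over the list alone (adjusted p = 0.910 with an estimated correlation). A second probe set of WNT7B rose by 1.02 and a dim one of WLS read 0.19. Immediate early genes had 3 of 20 higher, with KLF4 at 0.86, and 5 lower, with NR4A2 at -0.55, also adjusted over the list alone (adjusted p = 0.669 with an estimated correlation). NF-kB genes had NFKBIA higher (1.77) and IL1A lower (-0.55) of 18, also adjusted over the list alone (adjusted p = 0.928 with an estimated correlation). Interferon-stimulated genes had 0 of 19 called by limma and 8 at an unadjusted p below 0.05 (adjusted p = 0.717 with an estimated correlation). Among markers of other cells, ACTA2 fell (-0.73, 1 of 17 mesenchymal genes, also adjusted over the list alone, median 0.05 and mean -0.01) and STEAP1 rose (0.35, 1 of 10 prostate genes, also adjusted over the list alone). Of the others, 0 of 8 basal, 0 of 9 immune and endothelial and 0 of 11 housekeeping genes were called by limma, with 2, 0 and 5 at an unadjusted p below 0.05. Estimated correlations gave these 5 lists adjusted p = 0.959, 0.671, 0.741, 0.979 and 0.862. Without vehicle replicate 1 the calls of ERBB2, DUSP6, WNT7B, FZD4, WLS, NR4A2 and STEAP1 were lost, with a highest adjusted p over the fits without 1 array of 0.0589, 0.115, 0.264, 0.0656, 0.295, 0.165 and 0.275. Vehicle replicate 2 also ended the calls of ERBB2, DUSP6, WLS, STEAP1 and IL1A (0.0529), DHT 16 h replicate 1 those of DUSP6, WNT7B, WLS and STEAP1, DHT 16 h replicate 2 those of WNT7B, NR4A2 and STEAP1, and each 4 h and 48 h array those of WNT7B, WLS and STEAP1. The dimmer probe sets of ERBB2 had no call (-0.99 and -0.42).

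**Figure D3:**
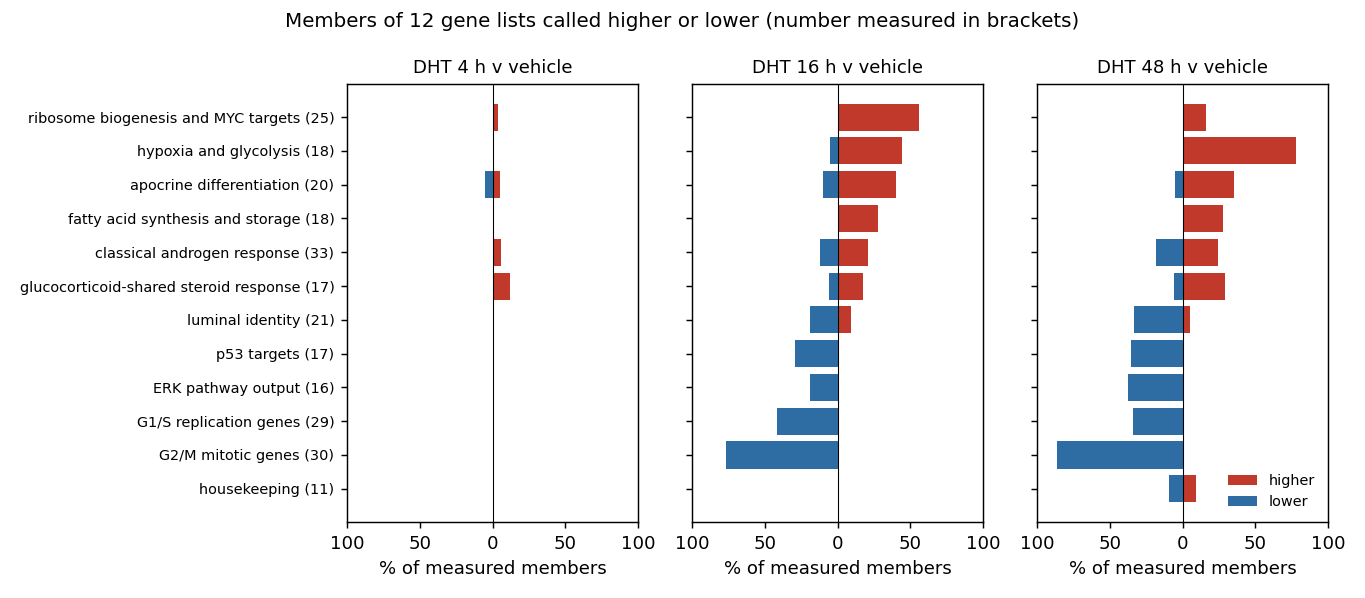
Percentage of measured members (horizontal axis) of 12 gene lists (vertical axis, number measured in brackets) called higher (red, right) or lower (blue, left) at 4, 16 and 48 h. G2/M mitotic genes had 23 of 30 members lower at 16 h and 26 at 48 h, and hypoxia and glycolysis genes 14 of 18 higher at 48 h.

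At 16 h 504 genes rose and 850 fell (3930 at an unadjusted p below 0.05). Other probe sets of the named genes, adjusted over all probe sets, were called in the same direction in 34 of 100 cases, and 0 in the opposite one. The count was 517 without vehicle replicate 1 (189 higher and 328 lower) and 1654 without DHT 16 h replicate 1 (762 higher and 892 lower). Without DHT 16 h replicate 2, the array whose 3′ and 5′ control probe sets differed most, it was 980 (248 higher and 732 lower). That array was singled out after the data had been seen.

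The comparison at 48 h asked what 48 h of DHT had changed. AQP3 stood 88.9-fold higher (log2 change 6.47 ± 0.10, SE, n = 2, adjusted p = 2.9e-11), and its 2 other probe sets gave 3.65 and 3.86. CYP4F8 stood 36.9-fold higher, MYBPC1 29.3-fold, UGT2B28 21.7-fold, CLDN8 14.2-fold, DDC 10.7-fold and FKBP5 10.1-fold. The other probe set of DDC had a smaller log2 change, 1.90. HSD11B2 had a log2 change of 3.46. PALLD fell by 4.35 log2 units (SE 0.13, adjusted p = 4.0e-09), a 20.4-fold reduction, while a dim probe set of another kind read -0.09. TNC fell 12.8-fold, CYP1A1 7.55-fold, SHISA2 6.91-fold and ANXA3 6.70-fold. DOCK2, an activator of the GTPase Rac, had a log2 change of -2.77, SIPA1L2 of -2.66 and AMIGO2 of -2.63. PHLDB2 had -2.47, EPPK1 -2.35 and PDE4B -2.12. Other probe sets of EPPK1 read -1.45 and -2.43, and further ones -0.22 and 0.10 with no call. The values were -1.97 for SEMA3C, -1.93 for FAM43A, -1.74 for MACC1, -1.59 for EPHA4 and -1.01 for PPFIBP2. MYC remained higher at 1.15, NFKBIA at 1.67, EAF2 at 1.16 and CCDC86 at 0.60.

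Of 30 G2/M mitotic genes, 26 fell at 48 h, 0 rose and 4 were not called, with 29 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). KIF23 (-1.16), AURKA (-0.98), KIF20A (-0.97), CCNA2 (-0.79) and DLGAP5 fell. Of 29 G1/S genes, 10 fell and 19 were not called, with 1 higher and 13 lower adjusted over the list alone (adjusted p = 0.231 with an estimated correlation). TYMS (-0.78), CCNE2 (-0.76) and TK1 (-0.64) fell, and RRM2 was not called (-0.28). The p53 targets had 6 of 17 lower, GDF15 (-1.60), TP53INP1 (-1.46) and CDKN1A (-0.61) among them, and 8 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). A dim probe set of GDF15 read 0.09. Ribosome biogenesis and MYC targets had 4 of 25 higher and 6 adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). WDR12 rose by 0.50 and ODC1 by 0.39, whereas NOP16 (0.33) and WDR43 (0.21) were not called. Without DHT 48 h replicate 1 the calls of CCNE2, AURKA, CDKN1A and ODC1 were lost, with a highest adjusted p over the fits without 1 array of 0.146, 0.0753, 0.0710 and 0.150. Vehicle replicate 1 also ended those of CCNE2 and ODC1, vehicle replicate 2 those of CDKN1A and ODC1, and DHT 48 h replicate 2 and each 4 h array that of ODC1.

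Hypoxia and glycolysis genes had 14 of 18 higher at 48 h, 0 lower and 4 not called, also adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). NDRG1 rose by 2.78, PDK1, a brake on pyruvate entry into mitochondria, by 1.68, P4HA1, a collagen prolyl hydroxylase, by 1.56, BNIP3, a mitophagy receptor, by 1.51, PFKFB4, a regulator of glycolysis, by 1.35, ANKRD37 by 1.30 and PGK1 by 0.46. Fatty acid synthesis and storage had 5 of 18 higher, ACACA (1.20), ACSL1 (1.03) and FASN (0.96) among them, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Cholesterol genes had 0 of 19 called by limma and 3 at an unadjusted p below 0.05 (adjusted p = 0.959 with an estimated correlation). The ATF4 list had 4 of 24 higher, with VLDLR at 2.12 and ASNS at 0.89, and 5 lower, and 4 higher and 6 lower adjusted over the list alone (adjusted p = 0.910 with an estimated correlation; median -0.02, mean 0.08). Endoplasmic reticulum folding had 2 of 21 higher, DNAJB9 (0.53) and PDIA4 (0.43), and 5 adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Steroid hormone metabolism had 3 of 21 higher, HSD11B2 (3.46), UGT2B28 and SRD5A1 (1.29), and 2 lower, with STS at -1.66, also adjusted over the list alone (adjusted p = 0.669 with an estimated correlation). Without DHT 48 h replicate 1 the calls of PGK1, DNAJB9 and PDIA4 were lost, with a highest adjusted p over the fits without 1 array of 0.0661, 0.0947 and 0.119. DHT 48 h replicate 2 and vehicle replicate 2 also ended those of DNAJB9 and PDIA4, and vehicle replicate 1 that of PDIA4. ASNS, P4HA1 and DNAJB9 had no call in probe sets outside the _s_at kind (adjusted p up to 0.776, 0.718 and 0.977). Those of ASNS and P4HA1 were dim, with mean log2 signals of 4.73 and 4.55, so they say little about these calls.

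Classical androgen response genes had 8 of 33 higher, FKBP5, NDRG1, IQGAP2 (2.69), AZGP1 (1.67) and ADAMTS1 (1.48) among them, 6 lower and 19 not called, with 10 higher and 6 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). KLK3 had 0.07 (adjusted p = 0.714). The glucocorticoid-shared list had 5 of 17 higher, with TSC22D3 at 0.74, and 1 lower, ERRFI1 (-0.80), and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Apocrine differentiation had 7 of 20 higher, with PIP at 1.24, and 1 lower, KMO (-1.80), and 9 higher and 6 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Luminal identity had 7 of 21 lower, among them TFF1 (-1.75), AGR2 (-1.43), the lineage factors GATA3 (-0.85) and FOXA1 (-0.72) and CLDN4 (-0.74), and 1 higher, KRT19 (0.68), with 4 higher and 9 lower adjusted over the list alone (adjusted p = 0.386 with an estimated correlation). ERK pathway output had 6 of 16 lower, EGR1 (-2.29), DUSP6 (-1.72), SPRY1 (-1.07) and IER3 (-0.99) among them, with 1 higher and 8 lower adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Other probe sets of EGR1 read -1.49, with a call, and -0.35, with no call. ERBB genes had 3 of 18 lower, ERBB2 (-0.65) and ERRFI1 among them, and 1 higher, the receptor inhibitor LRIG1 (0.62), with 3 higher and 4 lower adjusted over the list alone (adjusted p = 0.741 with an estimated correlation; median 0.01, mean -0.06), and ERBB3 had -0.05. The call of ERBB2 rested on the brightest of its 3 probe sets, since the mean of all 3 was not called (adjusted p up to 0.867), and TSC22D3 had none outside the _s_at kind (up to 0.398).

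Immediate early genes had 3 of 20 higher, with KLF4 at 1.29, and 6 lower, with NR4A2 at -1.16, and 3 higher and 7 lower adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). WNT ligands and receptors had 2 of 26 higher, WNT7B (0.66) and FZD4 (0.49), and 2 lower, with WLS at -0.45, also adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). The WNT/beta-catenin targets had MYC higher and 2 of 20 lower, with JAG1 at -1.17, also adjusted over the list alone (adjusted p = 0.875 with an estimated correlation). NF-kB genes had 1 of 18 higher, NFKBIA, and 1 lower, also adjusted over the list alone (adjusted p = 0.875 with an estimated correlation). IL1A was not called (-0.25). Interferon-stimulated genes had 3 of 19 lower, IFI6 (-0.59) and ISG15 (-0.54) among them, and 5 adjusted over the list alone (adjusted p = 0.643 with an estimated correlation; median 0.03, mean -0.09). Of the marker lists, basal genes had 1 of 8 higher, KRT5 (0.51), and 1 lower, CDH3 (-0.54), mesenchymal genes 1 of 17 lower, ACTA2 (-0.53), immune and endothelial genes 1 of 9 lower, CD2 (-0.33), and prostate genes 0 of 10 called by limma and 0 at an unadjusted p below 0.05, with the same counts adjusted over each list alone. Housekeeping genes had ACTB lower (-0.32) and PGK1 higher of 11, also adjusted over the list alone and under each scaling alternative (median -0.08, mean 0.00). With an estimated correlation these 5 lists had adjusted p = 0.913, 0.933, 0.910, 0.557 and 0.998. Without DHT 48 h replicate 1 the calls of WNT7B, FZD4, WLS, IFI6, ISG15, KRT5, ACTA2, CD2, ACTB and PGK1 were lost, with a highest adjusted p over the fits without 1 array of 0.0504, 0.0748, 0.175, 0.163, 0.108, 0.0760, 0.0503, 0.316, 0.172 and 0.0661. Vehicle replicate 1 also ended those of FZD4, WLS, IFI6, ISG15, KRT5, CD2 and ACTB, DHT 48 h replicate 2 those of FZD4, WLS, CD2 and ACTB, and vehicle replicate 2 and each 4 h array those of CD2 and ACTB.

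**Figure D4:**
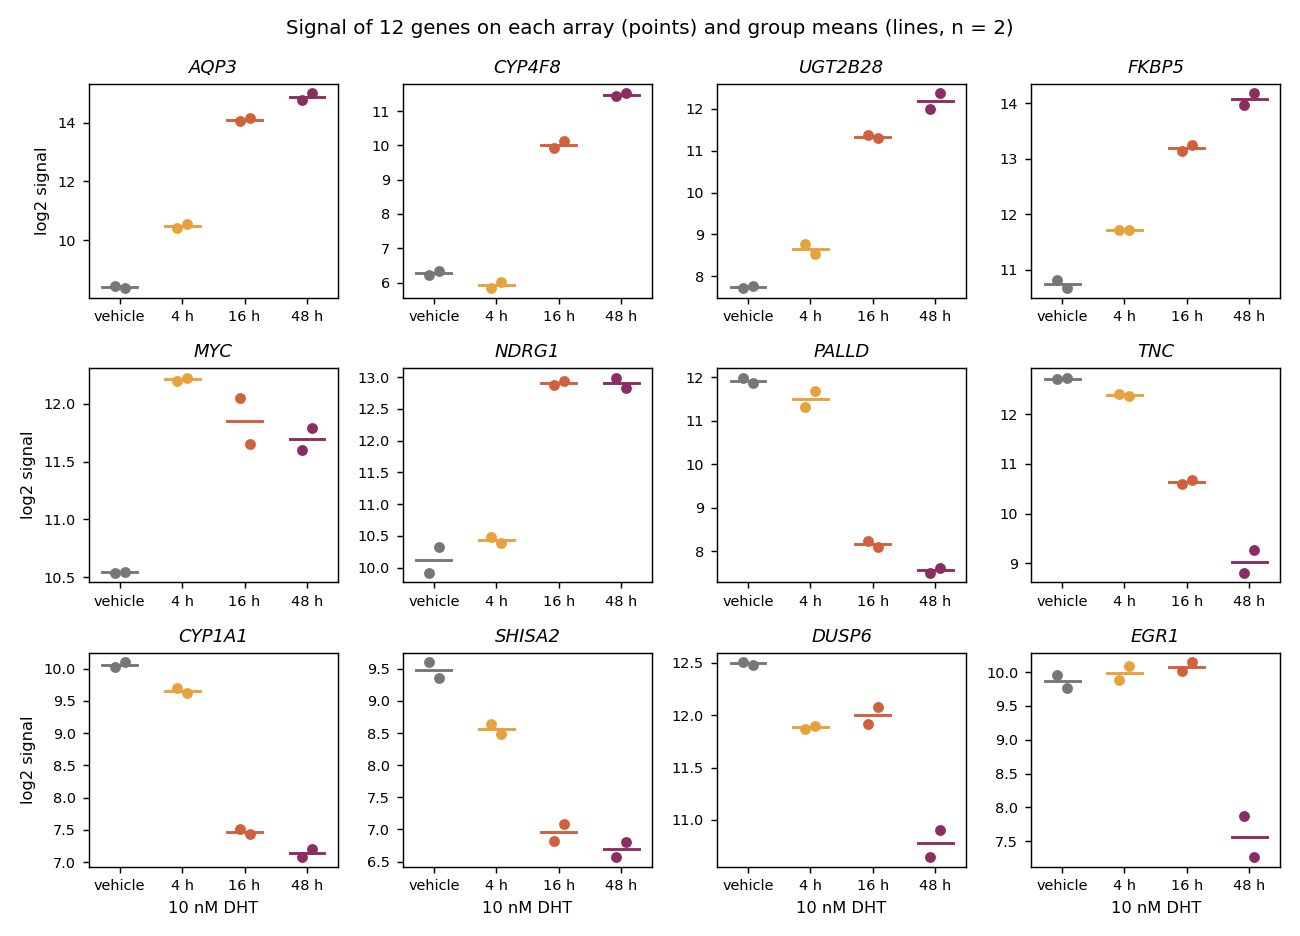
Log2 signal (vertical axis) of 12 genes on each array (points) in the vehicle group and after 4, 16 and 48 h of DHT (horizontal axis), with group means as lines, n = 2. AQP3 rose by 2.09, 5.69 and 6.47 at 4, 16 and 48 h, and EGR1 fell by 2.29 at 48 h, each read by its brightest probe set.

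At 48 h 619 genes rose and 1262 fell (4342 at an unadjusted p below 0.05), and 1760 genes changed at any time by the F test. Other probe sets of the named genes, adjusted over all probe sets, were called in the same direction in 55 of 110 cases, and 0 in the opposite one. The 48 h count was 834 without DHT 48 h replicate 1 (333 higher and 501 lower), 844 without vehicle replicate 1 (293 and 551) and 1325 without DHT 48 h replicate 2 (339 and 986). The count at any time was 1068 without vehicle replicate 1, 1034 without DHT 48 h replicate 1 and 1169 without DHT 4 h replicate 1.

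Comparisons between times set the DHT groups against each other. The vehicle arrays carry no time and cancel, so these differences mix any change in the effect of DHT with time in culture. From 4 to 16 h the highest differences were in CYP4F8 (log2 difference 4.09 ± 0.11, SE, n = 2), AQP3, UGT2B28 (2.69) and DDC (2.61), and the lowest in PALLD (-3.32), ANXA3 (-2.30), CYP1A1 (-2.18) and EPPK1 (-2.08). From 16 to 48 h MYBPC1 (2.36 ± 0.17), ANKRD37 (1.90), the protease inhibitor SLPI (1.54) and CYP4F8 (1.46) were highest, and EGR1 (-2.51 ± 0.17), TNC (-1.59) and AMIGO2 (-1.22) were among the lowest with DUSP6. From 4 to 48 h CYP4F8 (5.55), MYBPC1 (4.91), AQP3 (4.39) and UGT2B28 (3.53) were highest and PALLD (-3.92), TNC (-3.35), IGFBP3, which binds insulin-like growth factors (-2.58), and CYP1A1 (-2.51) were lowest. The counts were 254 higher and 350 lower from 4 to 16 h, 69 and 95 from 16 to 48 h, and 477 and 736 from 4 to 48 h. With values shifted to equal housekeeping signal the last became 399 and 1117, and from 16 to 48 h 66 and 162. Which direction had more genes was not stable from 16 to 48 h, and from 4 to 16 h it turned without DHT 16 h replicate 1. From 4 to 16 h the total was 1107 without DHT 16 h replicate 1 (594 higher and 513 lower), 417 without DHT 16 h replicate 2 (116 and 301), and 171 and 204 without DHT 4 h replicate 1 and 2 (78 and 93, then 73 and 131). From 16 to 48 h it was 644 without DHT 16 h replicate 1 (275 and 369) and 68 without DHT 16 h replicate 2 (45 and 23). It was 45 and 37 without DHT 48 h replicate 1 and 2 (31 and 14, then 21 and 16), and 97 without either 4 h array (49 and 48). From 4 to 48 h it was 490 and 577 without DHT 4 h replicate 1 and 2 (223 and 267, then 198 and 379), and 571 and 685 without DHT 48 h replicate 1 and 2 (273 and 298, then 217 and 468).

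Genes called early were mostly called later. Of the 21 genes higher at 4 h, 19 were called higher at 16 h and 16 at 48 h, and of the 14 lower, 12 were called lower at each later time. At 48 h, 10 of the 21 had a larger log2 change than at 4 h by the test of the difference, FKBP5 and AQP3 among them, and 5 had a lower log2 change. Of these MYC (log2 difference -0.52, adjusted p = 0.0337) was still called higher than vehicle at 48 h. The other 4 were named after their values were seen. FJX1, PUS1 and SINHCAF were no longer called (0.07, 0.22 and 0.21), and the retinol dehydrogenase RDH10 was called lower (-0.84). Of the 14 lower genes 9 had a larger and 2 a smaller effect, the latter MYCN (-0.63 at 4 h and -0.23 at 48 h) and STC1 (-0.60 and -0.10), also named after their values were seen. These 6 were not refitted without single arrays. The early genes were picked on the same 4 h arrays that the test of the difference uses. Smaller changes at 48 h may therefore come in part from that choice. Between 16 and 48 h, 963 genes were called in the same direction, 307 higher and 656 lower, which was 71.1% of the 16 h calls. Independent calls would give 15.8 and 54.2. The effects at 16 and 48 h correlated across genes at r = 0.822. Those at 4 h correlated at r = 0.570 with 16 h and r = 0.531 with 48 h. Simulated groups without change, which shared 2 simulated vehicle arrays, gave 0.501 each time. That value holds where no comparison has real changes, and real changes at only 1 of 2 times would lower r. An r near 0.501 therefore does not show that the 4 h effects were not shared. Because the comparisons shared 2 vehicle arrays, which were not divided because each part would hold 1 array, part of these overlaps may come from the controls. The covariance of 0.0628 at 16 and 48 h stood 0.0564 above the simulated one. For 4 and 16 h the covariance was 0.0217 and for 4 and 48 h 0.0233, which stood 0.0153 and 0.0169 above theirs. Without vehicle replicate 1 the 963 became 391, and without DHT 48 h replicate 1 560.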

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

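The 2 tests on DHT 16 h replicate 2 and the count of cytoskeletal genes at 16 h without it were chosen only after the results were seen, and the lists of serum response factor, YAP and TAZ, and further hypoxia-inducible genes were chosen after the data had been seen. Members of these lists were not refitted without single arrays, and VCL and CCN1 only without DHT 16 h replicate 2.

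The DHT groups differed between times, by the limma test of the difference itself and with time in culture not separated from DHT, for 604 genes between 16 and 4 h, 164 between 48 and 16 h and 1213 between 48 and 4 h. Among the named genes the log2 signal at 48 h stood above that at 4 h by 5.55 for CYP4F8, 4.91 for MYBPC1, 4.39 for AQP3, 3.53 for UGT2B28, 3.22 for DDC, 2.71 for HSD11B2, 2.67 for IQGAP2, 2.48 for NDRG1, 2.36 for FKBP5, 2.04 for CLDN8, 1.94 for SLPI and 1.82 for VLDLR. It stood above by 1.68 for PDK1, 1.67 for P4HA1, 1.63 for BNIP3, 1.59 for ANKRD37, 1.46 for AZGP1, 1.40 for PFKFB4, 1.26 for PIP, 1.18 for SRD5A1, 1.11 for ACACA, 0.92 for ASNS, 0.73 for KRT19, 0.70 for FASN, 0.69 for LRIG1 and ACSL1, 0.66 for ADAMTS1, 0.62 for KRT5, 0.60 for KLF4, 0.57 for DNAJB9, 0.56 for NFKBIA and PGK1, 0.48 for TSC22D3 and 0.45 for PDIA4. The difference was -3.92 for PALLD, -3.35 for TNC, -2.58 for IGFBP3, -2.51 for CYP1A1, -2.42 for EGR1, -2.30 for EPPK1, -2.25 for ANXA3 and -1.92 for SIPA1L2. Next were -1.88 for SHISA2, -1.78 for DOCK2, -1.68 for PHLDB2, -1.65 for AMIGO2, -1.59 for GDF15, -1.58 for MACC1, -1.43 for TFF1, -1.31 for SEMA3C, -1.20 for KMO, -1.14 for AGR2, -1.13 for JAG1, -1.12 for STS, -1.11 for DUSP6, -1.08 for NR4A2 and -0.98 for TP53INP1. Smaller ones were -0.95 for FAM43A, -0.93 for EPHA4, -0.92 for KIF20A, -0.88 for PDE4B, -0.87 for ERRFI1 and IER3, -0.85 for KIF23, -0.79 for TK1 and CCNA2, -0.78 for SPRY1 and DLGAP5, -0.69 for TYMS, -0.61 for GATA3, -0.53 for ERBB2, -0.52 for MYC, -0.50 for ISG15 and -0.41 for CDH3. Between 16 and 4 h it was 0.59 for EAF2, -0.84 for RRM2 and -0.53 for ACTA2, and between 48 and 16 h -0.53 for FOXA1.

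DHT 16 h replicate 2 stood apart in control probe sets outside the gene comparisons, with a 3′ minus 5′ difference of 1.52 for ACTB and 0.817 for GAPDH. Both lay above the highest of the other 7 arrays, the smaller excess being 0.468, but these are the values that drew attention to the array, so whether loss of signal far from the 3′ end explains its position stays open. A mislabelled or untreated sample is argued against, since the array followed the 48 h effect with a slope of 0.703, close to 0.740 for its replicate and far above 0.196 and 0.214 for the 4 h arrays. No biological explanation was tested for a single array. Leaving out this array or its replicate gave the same 48 h count, so a change in that count is not particular to this array.

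The cytoskeletal and matrix genes PALLD, TNC and ACTA2, and VCL and CCN1, chosen after their values were seen, were lower at 16 and 48 h. Loss of signal far from the 3′ end in DHT 16 h replicate 2 is argued against as the cause at 16 h, since 5 of the 5 were called lower without that array (PALLD -3.69, VCL -1.90, TNC -2.13, CCN1 -0.66 and ACTA2 -0.69). The 5 of 5 called at 48 h without it decide nothing, because that array does not enter the 48 h log2 changes. Among other serum response factor targets, genes of actin and contractility, 9 of 19 fell at 16 h and 9 at 48 h. At 48 h TPM4 had -1.46, MYH9 -1.33, ZYX -1.42, FHL2 -1.86 and PDLIM5 -1.82. TAGLN (0.25), TPM2 (0.09), MYL9 (0.16) and CALD1 (0.28) were not called. Camera with an estimated correlation gave an unadjusted p of 0.00589 at 48 h. The adjusted p of 0.0265 was taken over the added lists alone, and this list was chosen after the data had been seen. The test therefore cannot decide whether lower output of these targets is part of the pattern, which stays open. For the YAP and TAZ targets, of which 7 of 20 fell and 1 rose at 48 h, the unadjusted p was 0.0919 and the median -0.11, which neither bears out nor excludes a part for them. Fry for a shift in 1 direction gave this list adjusted p = 0.0042 over the added lists alone. Since the list was chosen after the data had been seen, that value does not decide it either.

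Of 18 hypoxia and glycolysis genes, 8 were higher and 1 lower at 16 h and 14 higher at 48 h, although the labels name no change in oxygen (adjusted p = 0.218 with an estimated correlation at both times). A list of 25 further hypoxia-inducible genes had 9 higher at 16 h and 13 at 48 h, 0 lower at either time, with 15 and 18 adjusted over the list alone. FAM162A (1.08), HILPDA (1.16), P4HA2 and BNIP3L (0.94) rose at 48 h. Camera with an estimated correlation gave this list an unadjusted p of 0.00102 at 48 h, against 0.00849 for the fixed list. Its adjusted p of 0.0183 was taken over the added lists alone and is not comparable with 0.218. The list was picked after the data had been seen, from genes of the same kind as the pattern. The counts show that the rise extended to further hypoxia-inducible genes, but they do not test a cause. Longer or denser culture of the treated cells than of the vehicle cells may raise such genes. Such a difference cannot be told apart from DHT, because 0 of the vehicle arrays carry a time in the labels. An effect of DHT stays among the open explanations.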

How the results depend on the processing

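Array weights, the crossed pairing of replicate numbers and list tests without single arrays were chosen only after the data had been seen. So was every rerun of the overlaps except that at adjusted p below 0.01. Of 196 calls of the 100 named genes, 119 were kept in every setting that could read them, 74 were lost in at least 1 and 5 turned. WLS and DNAJB9 at 16 h were lost in some settings and turned in another, so they stand in both of the last counts. The 5 turned with no _x_at or _s_at probe sets, which left dimmer probe sets: PALLD at 16 h (0.0123), WLS at 16 h (0.19), GDF15 at 16 h (0.12) and 48 h (0.0860), and DNAJB9 at 16 h (-0.0945). That setting gave 18, 894, 353 and 770 genes at 4 h, 16 h, 16 against 4 h and 48 against 4 h, 1139 at any time and an overlap between 16 and 48 h of 636. Fitting each comparison on its own 4 arrays gave 798 at 16 h, 302 for 16 against 4 h and 63 for 48 against 16 h. The probe set with the largest interquartile range gave 9 at 4 h, 324 for 16 against 4 h, 59 for 48 against 16 h, 802 for 48 against 4 h and 1167 at any time. Testing all probe sets gave 10 at 4 h and 92 for 48 against 16 h. A trended, robust prior gave 67 at 4 h and array weights 74. Asking for 1.5-fold gave 606 at 16 h, 851 at 48 h, 307 for 16 against 4 h, 564 for 48 against 4 h, 980 at any time and an overlap of 427, by its construction fewer. So did adjusted p below 0.01, with 9, 624 and 947 at 4, 16 and 48 h, 229, 59 and 607 for 16 against 4, 48 against 16 and 48 against 4 h, 891 at any time and an overlap of 457. List tests called 0 with an estimated correlation and 61 by fry in either direction. Except for the thresholds, the cause was not tested. Leaving out 1 array, which leaves a group with 1 array assumed to vary like the others, gave 5 (without DHT 4 h replicate 2) to 60 (without either 16 h array) at 4 h, 517 (without vehicle replicate 1) to 1654 (without DHT 16 h replicate 1) at 16 h and 834 (without DHT 48 h replicate 1) to 2211 (without either 16 h array) at 48 h. It gave 171 (without DHT 4 h replicate 1) to 1107 (without DHT 16 h replicate 1) for 16 against 4 h, 37 (without DHT 48 h replicate 2) to 644 (without DHT 16 h replicate 1) for 48 against 16 h and 490 (without DHT 4 h replicate 1) to 1494 (without either 16 h array) for 48 against 4 h. At any time it gave 1034 (without DHT 48 h replicate 1) to 2495 (without DHT 16 h replicate 1) and for the overlap 391 (without vehicle replicate 1) to 883 (without DHT 16 h replicate 1), and 23 to 27 list tests. The replicate block gave 25, 1261 and 1729 at 4, 16 and 48 h, 546, 135 and 1120 between times and 26 list tests. Deviations of same-numbered arrays correlated across genes at r = -0.24 to 0.20, so the numbers mark no shared day that could be seen, and the crossed pairing gave 41, 1524 and 1939. Quantile normalisation, cyclic loess, 2 shifts to a common level and a filter of genes below the 40th percentile kept each total within 1.5 times, but the housekeeping shift moved the higher genes at 4 h to 32, and the lower genes for 48 against 16 h to 162 and for 48 against 4 h to 1117. More genes were higher than lower for 48 against 16 h with each comparison fitted on its own (34 and 29), with the mean of all probe sets (64 and 54), with the largest interquartile range (36 and 23), over all probe sets (61 and 31) and at adjusted p below 0.01 (34 and 25). Of the named calls, 186 were in genes above that percentile and all 186 were kept there; signal over background limits the rest.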

Other observations

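The 3 lists in this part were chosen only after the data had been seen, and so were the genes singled out as turning direction.

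CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, fell at 16 and 48 h (log2 changes -2.59 and -2.92), and so did its relative CYP1B1 (-1.95 and -2.10). The other 5 members of the receptor's battery were not called at any time, among them NQO1 (0.05 at 16 h and -0.06 at 48 h) and TIPARP (0.08 and 0.09). The list had 0, 2 and 2 of 7 lower at 4, 16 and 48 h, and adjusted over the list alone 1, 2 and 2 lower and 1, 0 and 1 higher, with adjusted p = 0.138 and 0.188 with an estimated correlation at 16 and 48 h. Genes that estrogen induces in other breast cancer cells had 1 of 17 higher and 3 lower at 16 h and 2 higher and 4 lower at 48 h, with 2 and 3, then 3 and 5, adjusted over the list alone, where 1 was lower at 4 h (adjusted p = 0.637 and 0.488 with an estimated correlation). TFF1, AGR2 and the insulin receptor substrate IRS1 (-2.16 at 48 h) fell, and the secreted STC2 (0.58 and 0.99) rose. The median and mean of this list differed in sign at 4 h (0.01 and -0.02) and 16 h (0.10 and -0.10). GBP2, a guanylate-binding protein, fell at 16 and 48 h (-1.93 and -2.15). It was the 1 called member of 18 antigen presentation and guanylate-binding protein genes at each of these times, also adjusted over the list alone (adjusted p = 0.887 and 0.648 with an estimated correlation). That list had a median of 0.01 and a mean of -0.09 at 16 h. Fry for a shift in 1 direction, adjusted over the added lists alone, gave it adjusted p = 0.581 at 16 h and 0.113 at 48 h. The same test gave the receptor battery adjusted p = 4.1e-05 at both times. For the estrogen-induced genes it gave 0.0042 at 16 h and 0.00047 at 48 h. At 4 h the test of the serum response factor list pointed up while its median and mean were -0.01, and the YAP and TAZ list had a median of 0.02 and a mean of -0.02. Apart from CYP1A1, TFF1, AGR2 and ANKRD37, the genes of this part were not refitted without single arrays.

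The 4 genes called in opposite directions at 2 times were ANKRD37 (-0.60 at 16 h and 1.30 at 48 h), the chloride channel ANO1 (-0.60 and 0.43), the splicing factor SRSF6 (0.48 and -0.38) and RDH10 (0.56 at 4 h, -0.62 at 16 h and -0.84 at 48 h). The 16 h call of ANKRD37 was lost without vehicle replicate 1 (adjusted p = 0.105). Of 19775 genes, 17503 were called at none of the 3 times against vehicle, 643 were lower and 291 higher at 16 and 48 h but not at 4 h, and 605 were lower and 310 higher at 48 h alone. The mean signal of the hybridisation spike-in probe sets was 11.7 on vehicle replicate 1 and 12.3 to 12.6 on the other 7 arrays.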
